A study of Drosophila melanogaster with 6 samples.

How the data were processed

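Antennae of female Drosophila melanogaster were profiled by RNA-seq in 6 libraries, 3 from control flies and 3 from flies in which programmed cell death (PCD) was blocked in the antennae by p35, a baculoviral caspase inhibitor expressed from a UAS transgene. Per the labels, both groups carried the peb-Gal4 driver and an Or49a-GFP reporter, and each library came from the antennae of about 350 flies. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected, and libraries were made with a directional kit.

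The deposited values are read counts, whole numbers per gene, one file per library with no pooling. The submitters' processing notes name cutadapt 1.8, STAR 2.5.3a, HTSeq 0.9.1 and the BDGP6 genome build, without saying in what order or with which settings they were used. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and of a gene on the opposite strand that shares its exons may therefore be mixed, and reads of near-identical gene copies may be split or lost. Of the 133 genes chosen by the rule for named genes, 30 have exons opposite those of another gene and 11 share exon sequence with a gene on their strand. Each file lists 17698 gene identifiers, of which 17560 had a symbol and a position in the reference annotation of the BDGP6 assembly. Coordinates are those of that annotation, counted from 1.

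Each file also holds 5 rows that name no gene, such as reads that aligned to several places. These rows made up 11.9% to 13.5% of all counts per library and were left out of library sizes and tests. Gene counts per library ran from 15588725 to 17808516. A count of 3 in one library corresponded to 0.169 to 0.192 CPM. Intervals given for genes with 1 to 3 counts in a group are exact binomial 95% intervals on the pooled counts and cover counting error only. Replicates of a group differed by more than sampling noise in every comparison, with a chi-square per degree of freedom of 3.96 to 10.1, so no library appeared to have been deposited in duplicate.

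Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default expression filter by group, which kept 9181 genes holding 99.95% of gene counts. The sample pair given in the labels was a block in the model, because the series design text calls the design paired. p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold. Log2 fold changes are PCD-blocked minus control. Their standard errors were derived from the fold change and the test statistic. Means and standard deviations (SD) are over 3 libraries per group, of CPM, the count relative to the TMM-scaled library total. Adjusted p-values measure the spread between these pooled collections of flies.

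Of 24 gene lists fixed before the data were examined, 23 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01. The test was repeated with an estimated correlation, and fry (limma 3.58.1) was run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, so it has little power here. Camera compares a list with the other genes, whereas fry tests whether its members move, on balance, in 1 direction, so their p-values answer different questions. Genes named in the text were chosen by a rule fixed at the same time. The rule took the 10 strongest rises and the 10 strongest falls past the threshold with at least 1 CPM in the higher group and one direction in all 3 pairs. It added every receptor, co-receptor and gustatory gene past the threshold, the 4 antennal tuning receptors with the smallest p in each direction, and up to 4 members with the smallest p from each other list. It also took peb, Or49a, rpr, hid, grim, skl, Gr21a, Gr63a and Orco whatever their p. Or19b, Dcp-1, egr, Hsp83, Hsp27, Hsp67Bc, Ldh, puc, upd2, TotA, Mhc and the genes named with symbol families were outside this rule and were chosen after their values were seen.

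The gene test was tested on simulated counts for the 9181 genes with 200 changed genes in each of 5 draws. With trended dispersions it recovered 46.4% of genes changed 1.2-fold, 81.2% of those changed 1.5-fold, 87.6% of those changed 2-fold and 98.8% of those changed 4-fold, and 4.58% of calls were unchanged genes. With gene-wise dispersions 11.6% of calls were unchanged genes, above the nominal rate. In the data a far larger share of tested genes was called, 27.7%, so these rates need not hold for the real calls. The alternatives, fixed at the same time, were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no expression filter, a filter of at least 1 CPM in 3 libraries, no block, each pair left out, and scaling without genes above 1% of counts. Chromosome and neighbour tests used Python 3.11.15 and SciPy 1.17.1. The p35 transgene, the Gal4 driver and the GFP reporter have no row of their own among the genes analysed here. Checks that need a genome sequence, such as GC content, were not made.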

Results

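Transcript levels were measured by RNA-seq in whole antennae of adult females of 2 genotypes. PCD-blocked flies expressed the caspase inhibitor p35 under peb-Gal4, a driver inserted at the gene peb, and control flies lacked the p35 transgene. Each group had 3 libraries, matched in 3 sample pairs. Libraries held 15588725 to 17808516 gene counts, with the lowest total in PCD-blocked 1. The first principal component, with 57.0% of the variance, separated the groups. The second, with 22.3%, spread the PCD-blocked libraries, from PCD-blocked 1 at -24.0 to PCD-blocked 3 at 17.8, with controls from -8.26 to 7.54.

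The comparison asked which transcripts change in the antenna when p35 is expressed to block cell death. Of 52 tested antennal tuning receptor genes, 16 were higher and 19 lower in PCD-blocked antennae. Of the higher receptor genes 8 rose by more than 2-fold, among them Or42b (6.80-fold) and Or65b (3.93-fold), and of the lower ones 1 fell by more than 2-fold. The cell death genes rpr, grim and skl rose as well, and so did several inducible heat shock genes. In all, 1314 of 9181 tested genes were higher and 1225 were lower in PCD-blocked antennae (edgeR quasi-likelihood test, adjusted p under 0.05). Most changes were small: 1941 of the 2539 changed genes, or 76.4%, differed by less than 1.5-fold, while 225 rose and 95 fell by more than 2-fold. Of the changed genes, 2534 moved in one direction in all 3 pairs. The number of calls depended on the test and on pair 2: DESeq2 called 653 genes higher and 662 lower, and 753 and 728 genes passed without pair 2.

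Among the strongest rises, w (FBgn0003996, chromosome X, 2790599 to 2796466), the eye pigment transporter gene white, went from 60.0 ± 5.55 to 1918 ± 28.8 CPM (SD, n = 3 per group), a 32.0-fold rise with an SE of 0.06 on the log2 scale. It is also the common marker of fly transgenes, and reads from a transgene copy would be counted at this locus. Hsp70Bb (FBgn0013278, chromosome 3R, 12505793 to 12508139), an inducible heat shock gene with near-identical copies, rose from 0.0961 ± 0.0880 to 40.7 ± 2.91 CPM (log2 fold change 8.62 ± 0.21 SE). Its copy Hsp70Ba had 2 counts in all control libraries and 245 in PCD-blocked libraries, a ratio of 129 with a counting interval of 35.2 to 1068. Tektin-C, a gene for a ciliary microtubule protein, rose by 6.62 on the log2 scale to 25.4 ± 2.04 CPM. The zinc finger gene nerfin-1 rose by 6.05 to 9.31 ± 1.03 CPM, and ppk27, of the pickpocket sodium channel family, rose by 5.95 to 42.0 ± 3.59 CPM. Or33b rose by 5.61 and CG8620 by 4.45. CG15537 and CG12009 had 1 count each in the control libraries, with ratios of 71.4 (interval 12.4 to 2860) and 58.8 (interval 10.1 to 2362).

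The strongest falls were in low-abundance genes, many of them unnamed. The noncoding RNA gene asRNA:CR45822 (chromosome 3L, 7355717 to 7356598) went from 271 to 2 counts, a ratio of 129 with a counting interval of 35.4 to 1071, and CG30339 went from 133 to 1 count, a ratio of 127 with an interval of 22.4 to 5042. Counts fell from 77 to 2 for CG14572 (ratio 36.7, interval 9.82 to 308) and from 54 to 2 for CG42691 (ratio 25.7, interval 6.79 to 218). CG42691 shares exon sequence with CG42690 and CG43195 on its strand. The antisense gene asRNA:CR45835 fell by 4.51 on the log2 scale, CG13970 by 4.01, Mec2 by 3.68, Cyp6a16, a cytochrome P450 gene, by 3.15, CG30265 by 3.12 and CG42329 by 2.97. Both antisense genes lie opposite exons of other genes, CTCF for asRNA:CR45822 and Sec63 for asRNA:CR45835, and could not be separated from them if strand was not used in counting.

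Olfactory neuron types of the antenna are marked by the tuning receptor or receptors they express, so receptor transcripts were examined as a group. A neuron type can express more than 1 receptor, so counts of receptor genes are not counts of neuron types. Of 52 tested antennal tuning receptors, 16 were higher, 19 were lower and 17 did not pass (edgeR). Adjusted over the list alone, 16 were higher and 26 lower. The rises were larger than the falls: 8 receptors rose by more than 2-fold, while Ir76a was the 1 receptor that fell by more than 2-fold. Summed over the tested receptors, transcript levels were 2990 ± 137 CPM in controls and 2893 ± 87.5 CPM in PCD-blocked antennae (SD, n = 3).

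**Figure D1:**
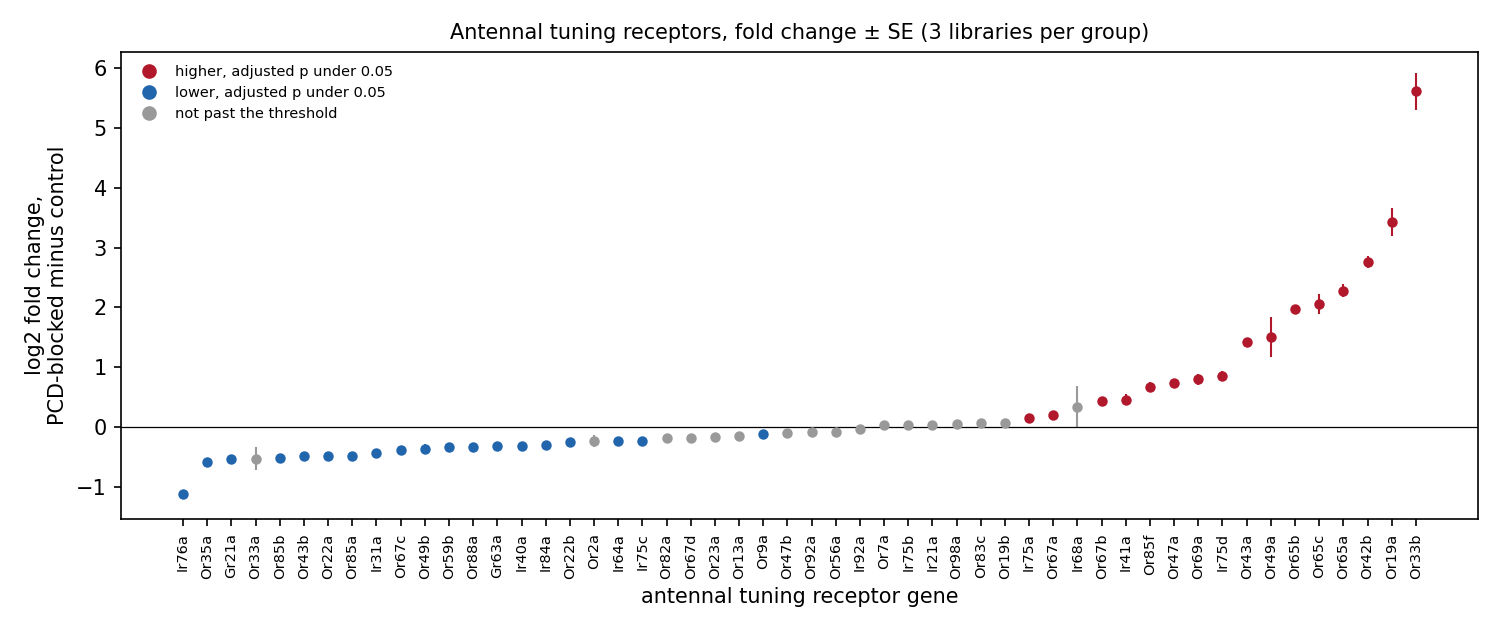
Log2 fold change (PCD-blocked minus control, vertical axis) of each of the 52 tested antennal tuning receptor genes (horizontal axis, ordered by value). Points are estimates from 3 libraries per group, bars are standard errors, and colours give the edgeR call. The 16 higher receptors reach 5.61 (Or33b), while the 19 lower receptors lie between -1.12 (Ir76a) and -0.11 (Or9a).

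The risen receptors belong to sensilla of several kinds. Or42b (FBgn0033043, chromosome 2R, 5797195 to 5798512), a receptor of basiconic neurons, rose from 16.3 ± 3.74 to 110 ± 2.10 CPM (log2 fold change 2.77 ± 0.10 SE, adjusted p = 7.36e-07 with edgeR). The trichoid receptor Or65b (FBgn0041624, chromosome 3L, 6325612 to 6327049) rose from 12.2 ± 2.05 to 47.6 ± 3.09 CPM (1.97 ± 0.07 SE, adjusted p = 6.79e-07 with edgeR), and the neighbouring Or65a and Or65c rose by 2.28 and 2.06 on the log2 scale. Or43a went from 20.7 ± 1.41 to 55.3 ± 5.05 CPM (log2 fold change 1.42 ± 0.07 SE). Or33b rose from 0.173 ± 0.115 to 8.87 ± 1.28 CPM. Or19a (chromosome X, 20141819 to 20143188) rose from 0.731 ± 0.259 to 7.91 ± 0.624 CPM (3.43 ± 0.23 SE), while its near copy Or19b had 40.4 ± 1.24 CPM in controls and 42.5 ± 1.23 CPM in PCD-blocked antennae and did not pass. Smaller rises were found for Ir75d (0.85), Or69a (0.80), Or47a (0.74), Or85f (0.68), Ir41a (0.46), Or67b (0.43), Or67a (0.20) and Ir75a (0.15). Or49a, the receptor whose promoter drives the reporter, rose from 0.520 ± 0.174 to 1.48 ± 0.177 CPM. That call was lost without pair 1 (adjusted p = 0.0597 with edgeR), without pair 2 (0.0866) and with DESeq2 (0.149), over a range of 0.00672 to 0.149 in the alternatives. The calls of Or67a and Ir75a were lost without pair 2 (adjusted p = 0.132 and 0.159 with edgeR) and without pair 3 (0.0979 and 0.125), with no block (0.0928 and 0.113) and with DESeq2 (0.265 and 0.0682), and that of Ir41a without pair 3 (0.0506) and with DESeq2 (0.120).

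The fallen receptors had control levels of 20.4 CPM (Or49b) or more. Ir76a (FBgn0260874, chromosome 3L, 19799278 to 19803427), an ionotropic receptor, fell from 45.7 ± 1.54 to 21.01 ± 1.26 CPM (log2 fold change -1.12 ± 0.06 SE, adjusted p = 3.91e-06 with edgeR). The carbon dioxide receptor genes Gr21a and Gr63a fell by 0.53 and 0.31 on the log2 scale. Or35a fell by 0.59, Or85b by 0.52, Or43b by 0.49, Or22a by 0.49, Or85a by 0.48, Ir31a by 0.44, Or67c by 0.39, Or49b by 0.36, Or59b by 0.33, Or88a by 0.33, Ir40a by 0.31, Ir84a by 0.30, Or22b by 0.25, Ir64a by 0.23 and Ir75c by 0.23. Or9a fell by 0.11, a call lost when any of the pairs was left out (adjusted p from 0.0752 to 0.251 with edgeR), with no block (0.179) and with limma-voom (0.0613), and without pair 2 those of Or49b (0.0765) and Or88a (0.0962) were lost too. DESeq2 did not call Or9a (adjusted p = 0.458), Or49b (0.131), Or88a (0.0903), Ir75c (0.0806) or Ir84a (0.0688), and Ir75c did not pass without the pair as a block (0.0554). Of the called tuning receptors, Ir75d shares exon sequence with COX6AL2 on its strand, and Ir75d, Ir76a, Or43b, Or47a, Or67b and Or88a have exons opposite those of other genes.

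By sensillum class, 8 of 23 basiconic Or genes were higher and 9 lower, and 5 of 13 trichoid and intermediate Or genes were higher and 1, Or88a, was lower. Of 13 antennal Ir genes, 3 were higher and 6 lower. Adjusted over the list alone, these counts were 8 and 12, 5 and 5, and 3 and 6. As a set, the trichoid and intermediate Or genes ranked higher than other genes (camera, adjusted p = 1.38e-05), with an adjusted p = 0.556 with an estimated correlation, 0.146 with limma-voom and 0.0655 with no expression filter. Their median log2 fold change was only 0.07, against a mean of 0.78. The 5 higher members were Or19a, Or43a and the neighbouring Or65a, Or65b and Or65c. The basiconic Or genes (adjusted p = 0.931), the antennal Ir genes (adjusted p = 0.0847) and the full receptor list (adjusted p = 0.758) did not pass camera. The antennal Ir list was called lower by camera without the pair as a block (adjusted p = 0.0445, in a range of 0.0445 to 0.556 over the camera alternatives). With fry, which tests for a change on balance in 1 direction and not against other genes, it had an adjusted p = 0.0121. The full list had a median of -0.10 and a mean of 0.31, so the 2 differed in sign, and the basiconic list likewise had a median of -0.09 and a mean of 0.37.

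Orco, the co-receptor shared by Or neurons, had 3012 ± 54.0 CPM in controls and 3098 ± 25.3 CPM in PCD-blocked antennae and did not pass (adjusted p = 0.382 with edgeR). Of 6 co-receptor genes, including the pheromone cofactor Snmp1, 4 were higher and 1 lower, and the counts were the same adjusted over the list alone. Ir25a rose by 0.45 to 576 ± 14.3 CPM, Ir93a by 0.50, Snmp1 by 0.38 to 1873 ± 62.9 CPM and Ir76b by 0.17, while Ir8a fell by 0.11. The Ir8a call was lost without pair 2 or 3 (adjusted p = 0.160 and 0.152 with edgeR), with no block (0.0506) and with DESeq2 (0.149), and that of Ir93a without pair 1 (0.0669) and with DESeq2 (0.0942). The list passed camera (adjusted p = 0.00842) and had an adjusted p = 0.556 with an estimated correlation. Of 9 tested gustatory receptors, 4 were higher and 0 lower, also adjusted over the list alone (5 did not pass). Gr43a, a fructose receptor, rose from 0.770 ± 0.135 to 9.23 ± 1.31 CPM (log2 fold change 3.57 ± 0.19 SE). Gr33a (2.53), Gr39a (2.51) and Gr32a (1.49) rose at 2.05 CPM or less, calls that DESeq2 did not make (adjusted p = 0.0639, 0.0681 and 0.0863); Gr32a was also lost without pair 2 (0.133) and pair 3 (0.0529). The gustatory list passed camera (adjusted p = 0.0466), with an adjusted p = 0.556 with an estimated correlation, 0.0524 with limma-voom, 0.133 with the stricter filter and up to 0.105 with 1 pair left out. Of the larval and palp Or genes, 5 of 20 were tested; Or1a rose by 1.27 and Or46a, which shares exon sequence with CG12917, fell by 0.39 (1 higher and 1 lower also adjusted over the list alone), and camera gave an adjusted p = 0.815. The Or1a call was lost without pair 1 (adjusted p = 0.0684 with edgeR) and pair 3 (0.0880), and DESeq2 called neither Or1a (0.238) nor Or46a (0.0507). With no expression filter the larval and palp list was called higher (camera adjusted p = 0.0413).

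**Figure D2:**
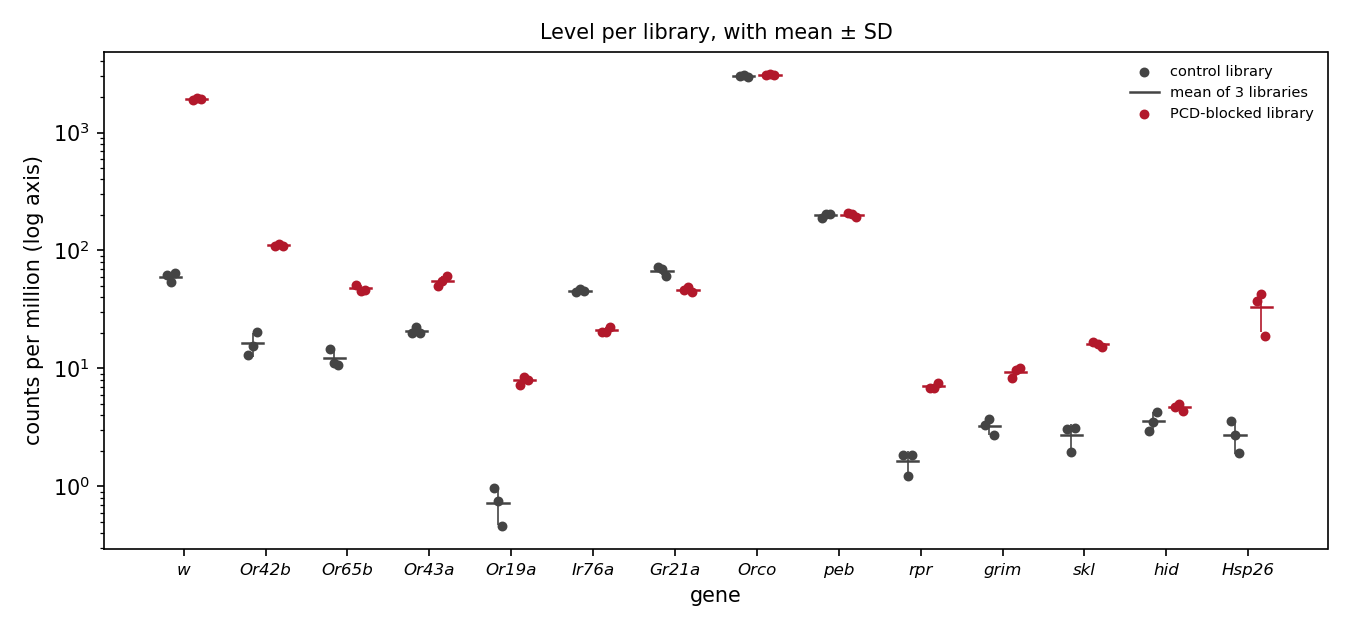
CPM on a log axis (vertical) in each of the 6 libraries for 14 genes (horizontal axis). Points are libraries, horizontal bars are group means and vertical bars are SDs over 3 libraries. Orco and peb differ little between groups, whereas w rises from 60.0 to 1918 CPM.

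Transcripts of the cell death genes were compared because p35 acts on caspases, downstream of the proapoptotic genes. The neighbouring genes skl, rpr and grim on chromosome 3L, which antagonise the caspase inhibitor Diap1, rose together. The level of skl went from 2.71 ± 0.646 to 16.1 ± 0.662 CPM (log2 fold change 2.57 ± 0.14 SE). That of rpr went from 1.63 ± 0.364 to 7.04 ± 0.375 CPM (2.11 ± 0.18 SE), and that of grim from 3.27 ± 0.526 to 9.37 ± 0.897 CPM (1.52 ± 0.15 SE). The fourth gene of this group, hid, had a log2 fold change of 0.40 ± 0.18 (SE) and did not pass (adjusted p = 0.130 with edgeR), but passed without pair 3 (0.0487). Of 22 tested members of the cell death machinery 5 were higher, 1 was lower and 16 did not pass, and 5 and 2 passed adjusted over the list alone, with 3 higher without pair 2 or with DESeq2. The other risen members were the caspase gene Dcp-1 (0.74) and egr (0.34), a tumour necrosis factor ligand, and grnd, a receptor for that ligand, fell by 0.26, a call that DESeq2 did not make (adjusted p = 0.0639). The list did not pass camera (adjusted p = 0.175), but did without pair 3 (0.0497).

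Of 14 genes of JNK and undead-cell signalling, 8 were higher and 0 lower, the same adjusted over the list alone (6 did not pass); without pair 2 the higher genes numbered 4 and with DESeq2 5. The cytokine genes upd2 and upd3 rose by 1.78 and 1.51 on the log2 scale, kay, which encodes Fos, by 0.29, the EGFR ligand gene Krn by 0.26 and the metalloprotease gene Mmp1 by 0.17, the last of which was lost without pair 2 (adjusted p = 0.0930 with edgeR). The standard JNK target puc had a log2 fold change of 0.01 and did not pass. Camera gave an adjusted p = 0.0270 and an adjusted p = 0.556 with an estimated correlation. The driver gene peb had 199 ± 8.84 CPM in controls and 201 ± 7.69 CPM in PCD-blocked antennae (log2 fold change 0.01 ± 0.04 SE) and did not pass.

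Of 18 tested transcription factors of olfactory neurons, 5 were higher and 5 lower, the same adjusted over the list alone, and camera gave an adjusted p = 0.538. The higher genes numbered 2 or 3 with 1 pair left out, 3 with no filter and 1 with DESeq2. The POU factor pdm3 fell by 0.30, bab2 by 0.27 and en, which encodes Engrailed, by 0.41, while the nuclear receptor gene svp rose by 0.42, a call that DESeq2 did not make (adjusted p = 0.132). Of 21 pan-neuronal genes 7 were higher and 0 lower (14 did not pass, and 7 and 0 passed adjusted over the list alone). The count of higher genes was 4 with any pair left out, with no block and with DESeq2, and 1 was lower without pair 1. Small rises were found for Cadps (0.29), Sh (0.23), unc-13 (0.17) and Rim (0.14), all synaptic or channel genes. Camera gave an adjusted p = 0.0560 for this list, and Rim did not pass without pair 1 (adjusted p = 0.0528 with edgeR) or pair 2 (0.116), or with no block (0.0774). The list was called higher with limma-voom (adjusted p = 0.0189), with no expression filter (0.00844) and without pair 3 (0.0497), in a range of 0.00844 to 0.556 over the alternatives. Of 9 mechanosensory genes of Johnston's organ, 3 were higher and 0 lower (4 and 0 adjusted over the list alone), and camera gave an adjusted p = 0.145. These were nompC (0.99) and nompA (0.78), which encode a mechanosensory channel and a dendritic cap protein, and nompB (0.19), which did not pass without pair 2 (adjusted p = 0.0517 with edgeR) or with DESeq2 (0.0785). The value for btv was 0.12, which did not pass.

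Heat shock and stress genes had the highest median log2 fold change of the lists, 1.83, and 0.87 ± 0.94 (SE) over the 10 members other than the Hsp70B copies. Of 13 tested, 8 were higher and 0 lower, and 9 were higher adjusted over the list alone (5 did not pass over all genes). Hsp26 rose from 2.73 ± 0.831 to 33.0 ± 12.5 CPM, Hsp23 from 3.08 ± 1.06 to 30.9 ± 13.8 CPM and Hsp68 from 7.96 ± 0.742 to 39.6 ± 12.0 CPM, with log2 fold changes of 3.58, 3.30 and 2.29. The abundant chaperone gene Hsp83 had 666 CPM in controls and 656 CPM in PCD-blocked antennae and did not pass. Camera gave an adjusted p = 6.62e-19, and the adjusted p = 0.237 with an estimated correlation. Among 7 tested immune effectors 4 were higher and 1 lower (4 and 2 adjusted over the list alone). The bomanin genes BomS3, BomS2 and BomS1, which encode secreted immune peptides, rose by 2.81, 2.64 and 1.57, and PGRP-SD, a peptidoglycan recognition gene, fell from 4.04 ± 1.36 to 1.51 ± 0.440 CPM. Camera gave an adjusted p = 0.0466, and adjusted p = 0.556 with an estimated correlation, 0.138 with limma-voom, 0.114 with no filter and 0.0622 without pair 1.

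Odorant-binding proteins are secreted by support cells of the sensilla. Of 19 tested, 2 were higher and 9 lower (2 and 10 adjusted over the list alone), and 4 to 10 were lower over the alternatives, with 4 without pair 2. The most abundant, Obp19d, fell from 21064 ± 530 to 15533 ± 280 CPM (log2 fold change -0.44 ± 0.03 SE), lush, which acts in pheromone sensing, fell by 0.39, Obp99d by 1.46, and Obp28a rose by 0.34 to 3889 ± 218 CPM. Camera placed the list lower (adjusted p = 0.0466), with an adjusted p = 0.556 with an estimated correlation and a range of 0.0161 to 0.556 over the alternatives. Of 83 ribosomal protein genes 29 were lower and 1 higher (31 and 1 adjusted over the list alone), a count of lower genes that dropped to 3 without pair 2, 10 without pair 1, 15 with no block and 17 with DESeq2. The members with the smallest p were RpL30 (-0.22), RpL39 (-0.21), RpLP0 (-0.20) and sta (-0.18). Camera gave an adjusted p = 6.37e-04, and adjusted p = 0.810 with an estimated correlation. Of 10 mitochondrially encoded genes, mt:ATPase6 (-0.25) and mt:ND5 (-0.21) were lower and 0 were higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.175). The values were -0.26 for mt:ND3 and -0.16 for mt:ND1, which did not pass. In the alternatives mt:ND3 passed with both other scalings (adjusted p = 0.0442 and 0.0427 with edgeR), both other filters (0.0385 and 0.0455) and limma-voom (0.0449), and mt:ND1 with no filter (0.0307) and without pair 3 (0.00432). Without pair 2, sta (adjusted p = 0.0897 with edgeR), mt:ATPase6 (0.0726) and mt:ND5 (0.186) did not pass, nor did mt:ND5 without pair 1 (0.0911). Neither mitochondrial gene passed with no block (0.0960 for mt:ATPase6, 0.114 for mt:ND5) or with DESeq2 (0.0793 and 0.196). DESeq2 did not call RpL39 (adjusted p = 0.0506), and it did not pass without the pair as a block (0.0923). The mitochondrial list was called lower with no expression filter (camera adjusted p = 0.0413) and without pair 3 (0.00965). Of 8 circadian clock genes 3 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.447). Here vri rose by 0.77, per by 0.42 and tim by 0.17, and cry, the blue light receptor gene, fell by 0.28. The tim call was not made without the pair as a block (adjusted p = 0.774 with edgeR, in a range of 0.00542 to 0.774 over the alternatives), and without pair 2 neither tim (0.0876) nor per (0.0717) passed. DESeq2 did not call per (0.0565).

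**Figure D3:**
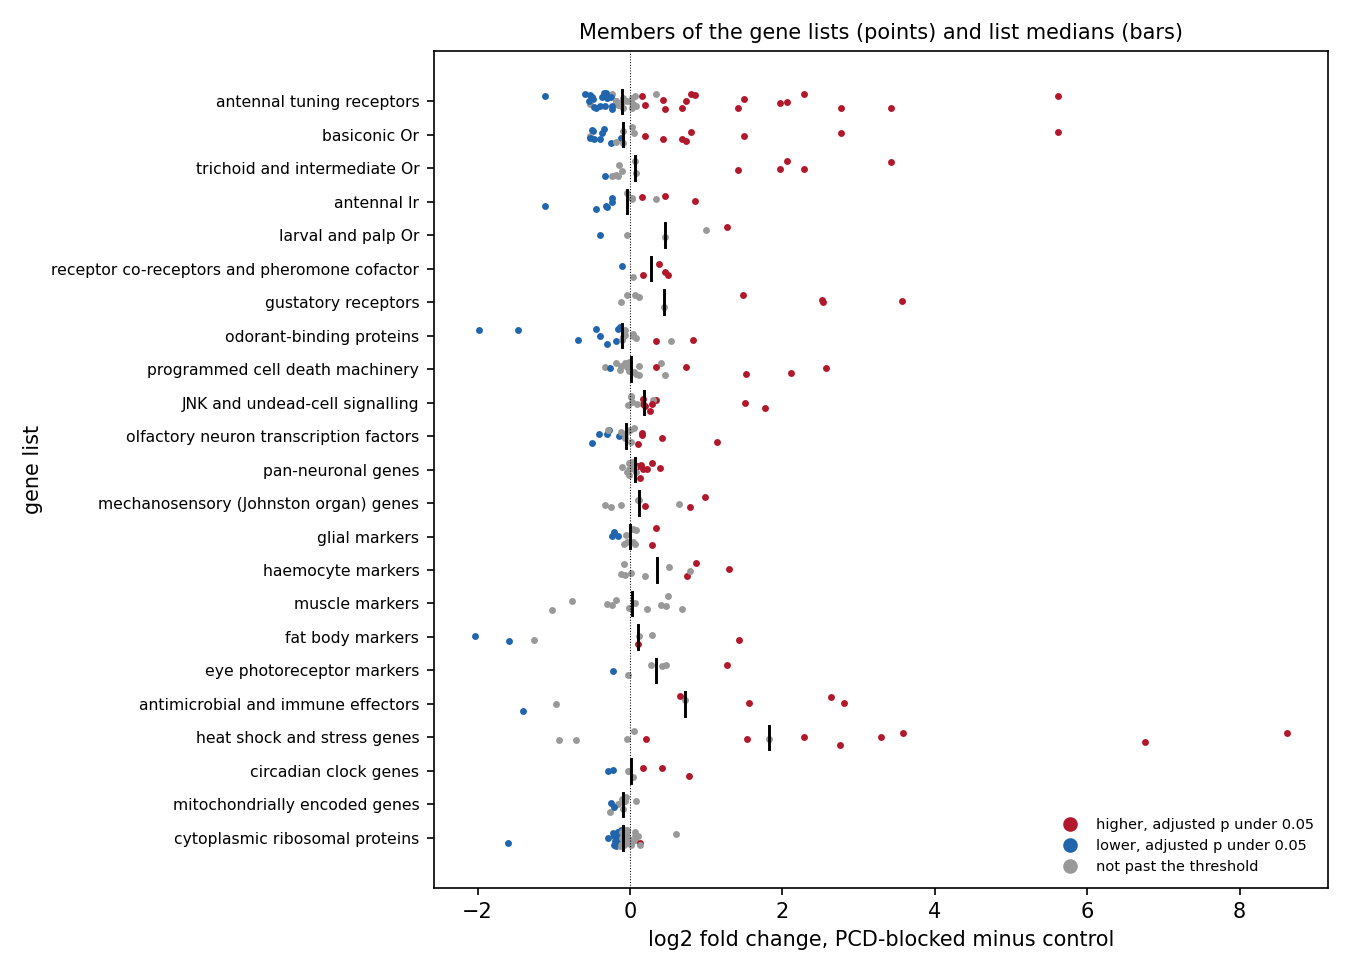
Log2 fold change (horizontal axis) of each tested member of the 23 gene lists tested as sets (vertical axis). Points are genes coloured by the edgeR call, and black bars are list medians. The heat shock list has the highest median, 1.83, and the ribosomal protein list has a median of -0.10.

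Markers of other cell types that the preparation could hold were compared in the same way. Of 12 glial markers 2 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.788): repo rose by 0.34 and Tret1-1 by 0.29, and Gs2 and axo fell by 0.24 and 0.21. Of 10 haemocyte markers 3 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.0466, and adjusted p = 0.556 with an estimated correlation). These were Pxn (1.29), Col4a1 (0.87) and vkg (0.74), all genes of basement membrane or matrix, whereas the haemocyte gene Hml had a value of 0.20 and did not pass. Without the pair as a block the haemocyte list had an adjusted p = 0.436 in camera (range 0.00958 to 0.556 over the alternatives), and Col4a1 and vkg did not pass (adjusted p = 0.0915 and 0.0624).

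Of 12 muscle markers 0 passed in either direction with edgeR, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 (DESeq2 and limma-voom 0, camera adjusted p = 0.985), and their levels varied between libraries of a group. The flight muscle gene up had values of 0.0637 and 0.231 CPM in PCD-blocked 1 and 2 and 3.71 CPM in PCD-blocked 3. Without pair 3 the list was called lower (camera adjusted p = 0.00579) and so was up (log2 fold change -3.96). The log2 fold changes were 0.47 for sls, 0.07 for Tm1 and -0.76 for TpnC4. Of these sls passed without pair 2 (adjusted p = 0.00293 with edgeR), with both other scalings and with both other filters (0.0130 and 0.0438). Of 7 fat body markers 2 were higher and 2 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.379). The lipoprotein gene apolpp rose from 20.2 ± 2.74 to 54.6 ± 1.09 CPM and the lipase gene bmm by 0.11. The yolk protein genes Yp3 and Yp2 fell by 2.04 and 1.59, but their level was uneven in controls: Yp3 had 70.6 CPM in control 1, 19.5 in control 2 and 9.24 in control 3. Without pair 1 neither passed (adjusted p = 0.0769 for Yp3 and 0.0506 for Yp2), without pair 2 neither passed (0.0988 and 0.0864), and DESeq2 called neither (0.0960 and 0.121). The bmm call was lost in every alternative except the stricter filter (adjusted p up to 0.480). Of 6 eye photoreceptor markers, trp rose by 1.28 and rdgA fell by 0.22 (1 higher and 1 lower also adjusted over the list alone, camera adjusted p = 0.649), and ninaC and Rh6 had values of 0.47 and 0.42 and did not pass. Of the male-specific markers 2 were tested, and lncRNA:roX1 rose by 0.15 (also adjusted over the list alone) while msl-2 had a value of 0.11 and did not pass. The lncRNA:roX1 call was lost with both other scalings (adjusted p = 0.0514 and 0.0524 with edgeR) and when any of the pairs was left out (0.0601 to 0.214), with no filter (0.0744), no block (0.370) and DESeq2 (0.535), and that of rdgA without pair 2 (0.0541).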

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

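The tests of library scaling, of Or19b, of the receptors as a set, of the heat shock genes, of transgene reads and of chromosome 2 against 3, and the stricter count of neighbours, were chosen only after the results were seen.

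Reads aligned to more than 1 place, which the comparisons above left out, made up 8.28% ± 0.241 of all counts in PCD-blocked and 7.45% ± 0.230 in control libraries (SD, n = 3), with all PCD-blocked libraries above all controls. Reads assigned to more than 1 gene made up 1.99% ± 0.00208 against 1.92% ± 0.00794. In both cases the exact permutation p, with the pairs ignored, was 0.1 (2-sided), the smallest that 3 against 3 libraries allow.

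The real grouping gave 2539 genes past the threshold, and the highest of the other splits of the 6 libraries gave 0 (edgeR, with 12 to 157 genes at an unadjusted p under 0.05). It was 1 of 10 splits with as many, and 10 splits are too few for a share under 0.05. Some splits parted only 1 pair, which leaves the blocked fit little to test. Without the block the real grouping gave 2134 genes and each other split 0. For gene lists at the preset correlation the real grouping gave 9 and the highest other split 6, again 1 of 10 splits.

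Of 52 tuning receptors 16 rose, 8 of them by more than 2-fold, while 19 fell and 17 did not pass. A scaling error alone would move all 52 alike and is argued against, since their log2 fold changes spread around their weighted mean with a chi-square per degree of freedom of 107 (91.4 or more with any 1 receptor left out). More neurons of every type would raise all 52 too, but their median was -0.10 ± 0.08 (SE). A net loss of reads from Or19b to Or19a was not seen, since Or19b changed by 2.16 ± 1.75 CPM (SD) as Or19a gained 7.18. This net value cannot exclude a shift of reads offset by a rise of Or19b. Nor does it cover reads aligned to more than 1 place, which were left out. A change of the genomic region was examined around the 8 receptors that rose by more than 2-fold, and it stays open. The 24 nearest tested genes outside the receptor families had a median absolute log2 fold change of 0.14 ± 0.05 (SE). That was above 80.7% of 2000 random sets and within its error of their 95th percentile, 0.176. Each random set took 8 genes drawn singly, whereas Or65a, Or65b and Or65c lie together and share neighbours. The random sets are therefore not fully alike to the observed one, and the percentile is approximate. The median can hide single loci: Ldh, adjacent to Or65a among tested genes, also rose by more than 2-fold. Survival of particular neuron types that would otherwise die is the biological explanation the design offers, and it remains untested here because counts do not separate more cells from more transcript per cell.

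The rise of w and Hsp70Bb may have a source in the p35 transgene, since fly vectors commonly carry a white marker and heat shock gene sequence. A heat shock response stays open as well. The 10 tested heat shock and stress genes other than the Hsp70B copies had a median log2 fold change of 0.87 ± 0.94 (SE). Hsp26 was at 3.58, Hsp23 at 3.30, Hsp67Bc at 2.76, Hsp68 at 2.29 and Hsp27 at 1.53, all past the threshold. In contrast, Hsp83 was at -0.04 and TotA at -0.93, and neither passed. The lowest PCD-blocked library had 0.867 of the highest for Hsp70Bb and 0.972 for w, against 0.443 for Hsp26. The near-identical copy Hsp70Ba, at lower levels, had 0.338, so the 2 Hsp70B copies differed. These values are given without deciding the matter. Reads of the transgene and of the endogenous genes cannot be told apart in gene counts.

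Strong changes lay next to each other on the chromosomes: 22 adjacent pairs of genes of different families both changed by more than 2-fold in one direction, against 6.31 on average and 11 at the upper end of the 95% range of 10000 shuffles. After leaving out unnamed gene pairs, the cell death genes and pairs with overlapping exons, 10 were left, against an average of 5.42 and an upper end of 10. Linked sequence differences between the genotypes may therefore contribute, or neighbouring genes may share regulation, and gene counts do not decide between them. Strong changes were not confined to chromosome 2. Changes of more than 2-fold were found in 3.42% of chromosome 3 genes (95% exact interval 2.88% to 4.03%) and in 3.91% of chromosome 2 genes. Fisher's exact test between these shares gave p = 0.266. The shares cannot show where the genotypes differ in sequence, because an effect of p35 could change transcripts from any chromosome.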

How the results depend on the processing

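Of 119 named genes past the threshold, 119 kept their direction in every alternative and 85 also stayed past the threshold in every one that tested them; 34 were lost in at least 1. DESeq2 lost 27, leaving out pair 2 lost 21 and fitting no block lost 14. The receptor counts ranged from 12 to 16 higher and 14 to 21 lower. The cause of the losses below was not tested, except that leaving out a pair leaves fewer samples.

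The counts of changed genes moved by more than 1.5 times with DESeq2 (653 higher, 662 lower) and ranged from 753 to 1065 higher and 728 to 1006 lower with 1 pair left out. The fit with no replicate block called 1124 and 1010. The labels call the samples pairs but do not say what a pair shared, and deviations from the group means correlated at 0.07, 0.24 and -0.19 within the 3 pairs, with 2 libraries correlating best with their own number.

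With an estimated correlation 0 of 23 lists passed (2 had an unadjusted p under 0.05, and fry passed 6). Few could pass, because camera then rests on 2 residual degrees of freedom. The heat shock list had an estimated correlation of -0.00399, below the preset 0.01. Its unadjusted camera p still went from 2.88e-20 to 0.0103, so correlated genes do not account for that loss. In this form of camera the adjusted p was 0.556 for the trichoid and intermediate, co-receptor, gustatory, odorant-binding, JNK, haemocyte and immune lists, 0.237 for heat shock genes and 0.810 for ribosomal proteins. With fry the odorant-binding (0.0944), JNK (0.0651), haemocyte (0.0826) and ribosomal protein (0.268) lists did not pass. With limma-voom the trichoid (0.146), gustatory (0.0524), haemocyte (0.0524) and immune (0.138) lists did not, and with no filter the trichoid (0.0655), haemocyte (0.0655), odorant-binding (0.0858) and immune (0.114) lists did not. The stricter filter ended the gustatory (0.133) and odorant-binding (0.0611) calls, and no block ended the odorant-binding (0.0708) and haemocyte (0.436) calls. With 1 pair left out the adjusted p ranged from 0.0409 to 0.105 for gustatory, 0.0161 to 0.194 for odorant-binding, 0.00958 to 0.0594 for haemocyte and 0.0161 to 0.0622 for immune genes.

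The direction of some lists that did not pass turned: the full receptor list (0.399 with limma-voom, 0.280 with no filter), the basiconic list (0.527 and 0.370, and 0.263 to 0.960 with 1 pair left out) and the eye list (0.995 with no filter). With 1 pair left out the same held for glial (0.534 to 0.962), muscle (0.00579 to 0.806) and fat body (0.0788 to 0.188) markers; muscle markers were called lower (0.00579) without pair 3. Some lists passed only in an alternative: antennal Ir with no block (0.0445) and, by its different test, fry (0.0121), pan-neuronal with limma-voom (0.0189), no filter (0.00844) and without pair 3 (0.0497), mitochondrial with no filter (0.0413) and without pair 3 (0.00965), larval and palp Or with no filter (0.0413) and cell death without pair 3 (0.0497). Among lists with at least 4 members called in a direction in the main fit, these counts moved by more than 1.5 times. Higher pan-neuronal genes numbered 4 with any pair left out, no block and DESeq2. Higher transcription factors numbered 3 without pair 1 or with no filter, 2 without pair 2 or 3 and 1 with DESeq2. Without pair 2 there were 4 JNK and 3 cell death genes higher and 4 odorant-binding genes lower; DESeq2 gave 5 JNK, 3 cell death and 1 gustatory gene higher, and the stricter filter 2 gustatory genes. Lower ribosomal genes numbered 10 without pair 1, 3 without pair 2, 15 with no block and 17 with DESeq2. Counts of lists with fewer calls in the main fit moved as well. Lower muscle genes went from 0 to 6 without pair 3. Lower mitochondrial genes went from 2 to 4 with no filter and without pair 3. Higher larval and palp Or genes went from 1 to 4 with no filter. The log2 fold change of up ranged from -3.96 to 0.0547 and that of peb from -0.0481 to 0.0664. Depth limits genes under about 0.2 CPM, where a library holds about 3 counts.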

Other observations

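The tests of gene families, named by the start of their symbols, and the genes named with them were chosen after the data were seen. Among 55 families with at least 8 tested genes, tested in both directions (110 Fisher's exact tests with Benjamini-Hochberg adjustment), several had more calls than other genes. Fisher's test treats genes as independent, so its p-values are too small where members of a family change together. The ribosomal RpS and RpL families also passed it as lower (adjusted p = 0.00669 and 0.0461). In camera the ribosomal list had an adjusted p = 0.810 at its estimated correlation of 0.850. Of 19 dpr genes, which encode neuronal surface proteins of the immunoglobulin superfamily, 10 were higher and 0 lower (adjusted p = 0.00515, with 6 to 10 higher over the alternatives), led by dpr11, which rose from 63.0 to 111 CPM. Of 13 ppk genes, 7 were higher and 1 lower (adjusted p = 0.0146, with 3 to 7 higher over the alternatives), among them ppk27, ppk24 (log2 fold change 3.26) and ppk14 (1.75). Of 11 GstD glutathione transferase genes, 6 were higher and 0 lower (adjusted p = 0.0226), with GstD5 at 1.94, GstD10 at 1.48 and GstD2 at 0.76. Of 10 Vha genes, which encode subunits of the vacuolar proton pump, 6 were higher and 0 lower (adjusted p = 0.0146), with a median of 0.15; this count fell to 1 in the least favourable alternative.

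Other families had more genes lower. Of 64 genes with symbols starting in Cyp, 24 were lower and 11 higher (adjusted p = 1.07e-04), and the count of lower genes ran from 20 to 25 over the alternatives. Most are cytochrome P450 genes, but Cyp1 and Cyp40 encode cyclophilins, and Cyp1 (log2 fold change -0.24) was among the lower genes. The counts and the p-value are therefore not those of P450 genes alone. Of 11 Spn serpin genes, 7 were lower and 0 higher (adjusted p = 0.00549, with 4 to 7 lower over the alternatives), with Spn42Dd at -0.61. Of 10 alpha-Est esterase genes, 6 were lower and 0 higher (adjusted p = 0.0133), with alpha-Est2 at -0.79, and 6 were lower in every alternative. Of 21 Ugt genes, 8 were lower and 2 higher (adjusted p = 0.0325), and of 13 GstE genes, 6 were lower and 2 higher (adjusted p = 0.0325).

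Levels of tim, a clock gene whose transcript cycles over the day, followed the sample pair more than the group. They were 170 and 154 CPM in PCD-blocked 1 and control 1, 124 and 104 CPM in PCD-blocked 2 and control 2, and 277 and 252 CPM in PCD-blocked 3 and control 3. The matrix gene Col4a1 had 30.9 and 17.8 CPM in the PCD-blocked and control library of pair 1, 47.3 and 22.8 CPM in pair 2, and 71.8 and 41.8 CPM in pair 3. The muscle gene Mhc was at 21.6 CPM in PCD-blocked 3 and 16.9 CPM in control 2, and at 2.93 CPM or less in the other libraries.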
